A study of Homo sapiens with 6 samples.

How the data were processed

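RNA bound by myc-tagged NSUN2 C271A in HEK293 cells was measured by miCLIP in 6 libraries, which the labels call replicates 1 to 6 of 1 group. Per the labels' protocols, cells were harvested 24 h after transfection, lysates were treated with DNase and little RNase I, and complexes were isolated with an anti-myc antibody on protein G beads. A linker was ligated to the RNA, and complexes were resolved on gels and moved to nitrocellulose. RNA was freed with proteinase K and reverse transcribed with primers carrying a 5-nt random barcode, which traces single cDNAs. The cDNA was circularised, cut open and amplified by 25 or 35 cycles of PCR. The labels' protocols also describe oligo-dT purification and an mRNA library kit, and whether these steps applied to the miCLIP libraries is not given in the sources used here.

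Per the submitters' processing notes, Bowtie 0.12.9 and the human build GRCh37 (hg19) were used. The deposited values are whole-number counts per noncoding RNA entry, with no normalization by the authors that the values show. The annotation, the treatment of reads matching several places, the filters and the use of the random barcodes are not given in the sources used here. The deposited tables hold 634 entry names, of which 423 are tRNA entries named by chromosome, number, isotype and anticodon. Replicates 1 and 4 list 522 entries and the 4 others list 634, and the 522 are contained in the 634. The 112 entries outside the shorter list carried 172 counts in all, at most 11 in a library. An entry without a value was read as 0 counts. Columns that belong to no sample numbered 0.

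Entries were put into classes by their names and symbols. Of 151 Ensembl gene IDs, 135 were paired with a symbol in the gene name table and 16 were not, and 32 other names were matched to a symbol in the RefSeq gene table of the GRCh38.p14 assembly, which was used for names only. The tRNA names gave 51 anticodon names, and the anticodon of 3 entries was undetermined.

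From the counts, each entry's share of its library's total was computed in percent, and shares were summed per class, per list and, within tRNA, per isotype and anticodon. Means and SDs are over libraries. Intervals of a share in 1 library are 95% Wilson intervals, and the limit of a count of 0 is 3 counts of the total. Both cover counting error only. Depth set the precision. A count of 3 was 0.00237% of the total in replicate 1 and 0.000221% in replicate 4.

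Pairs of RNAs or groups were compared within libraries by the log2 ratio of their counts. For the vault RNA ratios and for tRNA against all other entries, 0.5 counts were first added to each side. The test was an exact two-sided sign-flip permutation test over the 64 sign patterns of 6 libraries, whose smallest p is 0.03125. The threshold was 0.05. Agreement of the anticodon order was measured by Kendall's W with 100000 permutations. Pairs of libraries were compared by Pearson and Spearman correlation of log2(CPM + 1), where CPM is the share scaled to a fixed total and by a chi-square test over entries with an expected count of at least 5 in both, which covers counting error only. Overlap of entry lists was set against 1000 random lists. Values in which 1 library lay far from the 5 others were sought with Dixon's ratio. The split by totals was placed at the widest gap in log total count. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

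The scripts were tested on simulated data. For 634 entries drawn from 1 composition at the real totals, 15 of 15 pairs had a chi-square p over 0.05, with at most 1.07 per degree of freedom, and with 200 entries changed 1.5-fold 5 of 5 pairs were told apart. The sign-flip test called 0.0265 of null draws. A simulated log2 ratio of hsa-vault-1 to VTRNA1-3 of 3 came back as 2.98.

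The comparisons, the tests, the lists of RNAs, the naming rule and most alternatives were fixed before the data were examined. For tRNA the plan set the leading isotype against the next, and the ranking in these data picked the pairs of isotypes and of anticodons. The naming rule took the 5 RNAs with the highest mean share in each class among those found in all 6 libraries, all vault RNAs, and all other RNA polymerase III RNAs with at least 3 counts in a library, of which the text names the leading ones and counts the rest. The comparison of tRNA with all other entries, the split by totals, the removal of Leu(CAA) entries and the minimum of 10 expected counts for comparing anticodons between the sets were added after seeing the data. Alternatives were leaving out each library, other pseudocounts, count minimums, pooled counts, medians, shares of entries in place of counts, shares outside tRNA and means per listed tRNA entry. A planned comparison of tRNA with protein-coding RNA, the NSUN2 transcript, VTRNA2-1, lists of protein-coding, mitochondrial and long noncoding RNAs, and the positions of crosslinks were not analysed here. The planned list of other RNA polymerase III RNAs also named RPPH1, RMRP, RN7SL1 and RN7SL2, which the class used here did not cover.

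Whether the trailing number in the names of the tables pairs libraries was checked on the 40 leading anticodons. Tables with the same trailing number, replicates 1 and 4, 2 and 5, and 3 and 6, had correlations of their deviations from the set means of -0.0177, -0.0725 and -0.457. Other pairs across the sets ran from -0.585 to 0.612, with 0.612 for replicates 3 and 4, 0.462 for 2 and 6 and 0.111 for 1 and 5. Replicates 1 and 4 also share the list of 522 entries, which no other library has, while the 634-entry list does not separate the other pairs. Libraries were not paired, because no label gives a pairing. Neither the correlations nor the lists settle whether any libraries share cDNA.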

Results

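In human embryonic kidney HEK293 cells that carried a myc-tagged C271A form of the cytosine-5 RNA methyltransferase NSUN2, the RNA recovered with the enzyme was almost entirely tRNA among the noncoding RNAs listed. Leucine tRNAs with the CAA anticodon held the largest part of the tRNA counts in every library. By mean share over all 6 libraries the Ser(AGA), Met(CAT) and His(GTG) tRNAs came next. Which anticodons followed Leu(CAA) depended on the libraries used. Of the entries not named as tRNA, the microRNA-type entry MI0016077 had the highest mean share. The vault RNA entry hsa-vault-1 came next in the 3 libraries with the lower totals. In the 3 with the higher totals hsa-mir-1274b came next. There hsa-vault-1 followed it by mean share, but stood below the microRNA-type entry MI0016887 in replicates 4 and 5. The entry hsa-mir-1274b is listed as a microRNA but is a lysine tRNA fragment by later annotation. The C271A change replaces the cysteine that NSUN2 uses to let go of its substrate, so the enzyme stays covalently bound to the cytosine it attacks. The miCLIP method is meant to read out the RNAs held in this way. Without a mock library, such RNAs cannot be told apart here from background. Cells were harvested 24 h after transfection, the RNA was partly digested, and the enzyme with its RNA was pulled down with an anti-myc antibody. The study set out to find NSUN2 targets, and its title names vault RNA.

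The data comprised 6 replicate libraries of this single group, with no mock, untagged or wild-type NSUN2 library, so every comparison was made between RNAs within the same libraries. Total counts were 126556, 325811, 129194, 1358425, 1242931 and 889447 in replicates 1 to 6, a 10.7-fold range. Replicates 1, 2 and 3 had the lower totals and replicates 4, 5 and 6 the higher ones, with a 2.73-fold gap between the sets. The protocol names PCR at 25 or 35 cycles, and the deposited tables of replicates 1 to 3 carry the number 25 in their names and those of replicates 4 to 6 the number 35. The labels do not say whether that number is the cycle number. Values within each set are therefore given for each ratio tested and for several shares that differed between the sets. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels also leave open whether the tables with 35 come from second amplifications of the cDNAs behind those with 25. With only 3 independent samples, the smallest exact p of the tests below would be 0.25.

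Transfer RNA, the best known NSUN2 substrate class, held 97.8% ± 0.0948 (SD, n = 6) of the counts, between 97.7% and 97.9% per library, over 423 entries. All microRNA entries together held 1.74% ± 0.111 (n = 6), and the 4 vault RNA entries 0.367% ± 0.126 (n = 6). The other RNA polymerase III transcripts, counted here as the 5S rRNA, 7SK, Y RNA and U6 families, held 0.0335% ± 0.00692 (n = 6) over 86 entries. RPPH1, RMRP, RN7SL1 and RN7SL2, also on the planned list, were not assigned to this class, so its share may be too low. Small nuclear, small nucleolar and small Cajal body RNAs, which guide or carry out RNA splicing and modification, held 0.0173% ± 0.00601 (n = 6) over 73 entries, with means of 0.0127% in the lower-total and 0.0219% in the higher-total libraries (n = 3 each). The tRNA counts exceeded all other counts by a log2 ratio of 5.45 ± 0.0638 (SD, n = 6), in 6 of 6 libraries (exact two-sided sign-flip permutation p = 0.03125, the smallest that 6 libraries allow). This ratio was 5.46 ± 0.0966 (n = 3) in the libraries with the lower totals and 5.45 ± 0.0263 (n = 3) in those with the higher totals. The comparison covers only the noncoding RNAs that the tables list, and protein-coding RNAs were not analysed here. It was added after seeing the data, so its p-value is no independent support. Without a mock library or a library of unselected RNA, the lead of tRNA cannot be told apart from abundance in the cells. Classes follow entry names, so a tRNA fragment listed as a microRNA, such as hsa-mir-1274b, counts among the other entries.

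**Figure D1:**
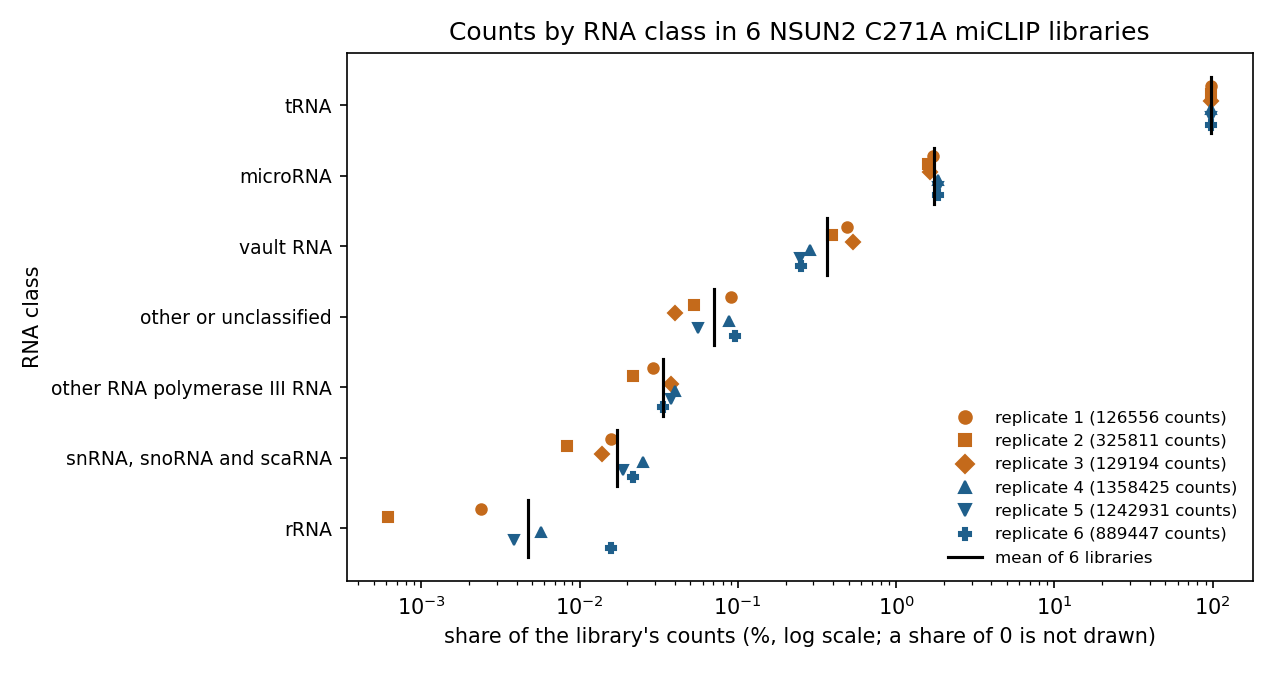
Share of each library's counts (percent, log scale, horizontal axis) for 7 RNA classes (vertical axis). Each symbol is 1 of 6 NSUN2 C271A miCLIP libraries, orange for the 3 with the lower totals and blue for the 3 with the higher totals, and the black line is the mean. The tRNA points lie between 97.7% and 97.9%, and the vault RNA points of the 3 lower-total libraries lie above those of the other 3.

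Vault RNAs, small noncoding transcripts of RNA polymerase III that are part of the vault ribonucleoprotein particle, were led by hsa-vault-1 in every library. This entry held 0.285% ± 0.132 (SD, n = 6) of all counts, against 0.0674% ± 0.00835 (n = 6) for VTRNA1-3 (ENSG00000202515) and 0.0147% ± 0.00572 (n = 6) for VTRNA1-2 (ENSG00000202111). The hsa-vault-1 share was 0.398% ± 0.0713 in the lower-total and 0.172% ± 0.00949 in the higher-total libraries (n = 3 each). The counts of hsa-vault-1 in replicates 1 to 6 were 525, 1043, 594, 2483, 2082 and 1471. The fourth vault entry, VTRNA3-1P (ENSG00000199422), had 2 counts in all libraries together. The tables give hsa-vault-1 no gene symbol; it is read here as vault RNA 1-1 because VTRNA1-2 and VTRNA1-3 have entries of their own, and this reading was not tested.

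Compared within libraries, hsa-vault-1 exceeded VTRNA1-3 3.87-fold, a log2 ratio of 1.95 ± 0.74 (SD, n = 6), and VTRNA1-2 18.9-fold, a log2 ratio of 4.24 ± 1.23 (n = 6). Each was higher in 6 of 6 libraries (exact two-sided sign-flip permutation p = 0.03125, Benjamini-Hochberg adjusted p = 0.03125 over the 2 comparisons). VTRNA1-3 in turn exceeded VTRNA1-2 by a log2 ratio of 2.29 ± 0.65 (n = 6, exact permutation p = 0.03125, 6 of 6 libraries). That comparison was not in the plan and its p-value was not adjusted, so the p-value is no independent support for this order. The size of the lead moved with the set of libraries. The log2 ratio of hsa-vault-1 to VTRNA1-3 was 2.61 ± 0.23 (n = 3) in the libraries with the lower totals and 1.30 ± 0.16 (n = 3) in those with the higher totals. For VTRNA1-2 the corresponding values were 5.26 ± 0.78 and 3.22 ± 0.17 (n = 3 each). They rest on few VTRNA1-2 counts in the lower-total libraries, with 21, 31, 8, 288, 235 and 138 in replicates 1 to 6. With 3 libraries the smallest exact p is 0.25, so neither set alone can pass the threshold.

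The whole vault RNA class held 0.473% ± 0.0730 (n = 3) of counts in the lower-total libraries and 0.261% ± 0.0224 (n = 3) in the higher-total ones. This difference lay in hsa-vault-1. In the same order, VTRNA1-3 held 0.0642% and 0.0705% and VTRNA1-2 0.0108% and 0.0185% (n = 3 each), and both overlapped between the sets. Counting error was small beside the gap of the class. The 95% Wilson interval of the vault share in replicate 2, the lowest of the first 3, was 0.372% to 0.415%, and that in replicate 4, the highest of the other 3, was 0.278% to 0.296%. These intervals cover counting error only, because whether PCR copies were collapsed by their barcodes is not given in the sources used here.

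**Figure D2:**
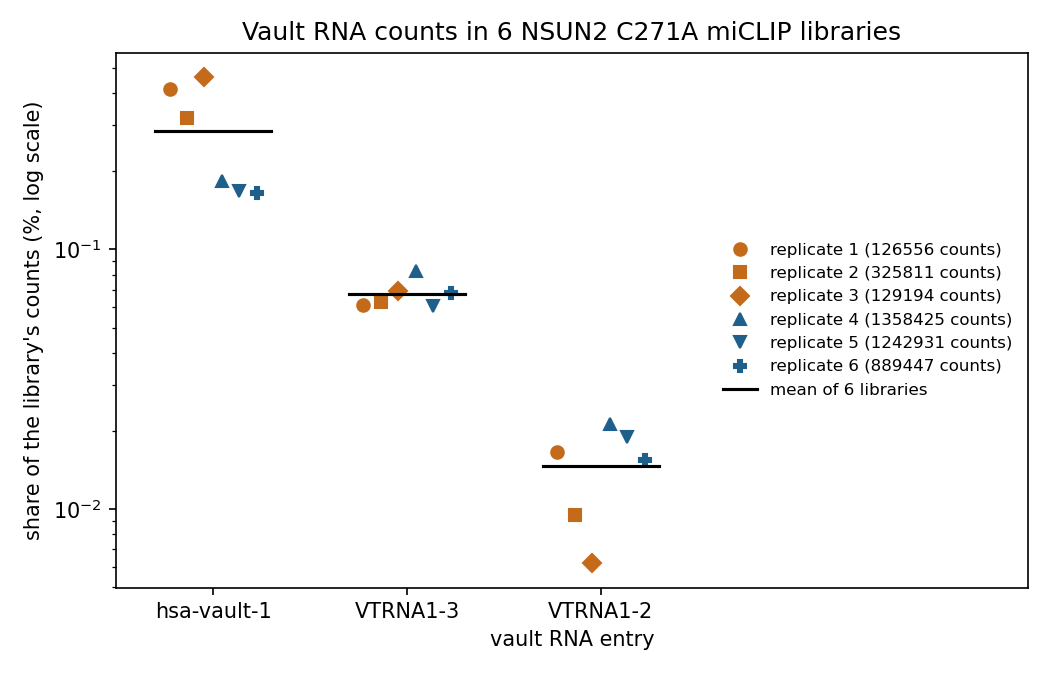
Share of each library's counts (percent, log scale, vertical axis) for 3 vault RNA entries (horizontal axis). Each symbol is 1 of 6 libraries, orange for the 3 with the lower totals and blue for the 3 with the higher totals, and the black line is the mean. The means are 0.285% for hsa-vault-1, 0.0674% for VTRNA1-3 and 0.0147% for VTRNA1-2.

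Among tRNAs, leucine tRNAs held 27.2% ± 3.70 (SD, n = 6) of the tRNA counts and serine tRNAs 16.7% ± 3.05 (n = 6). Threonine tRNAs followed with 7.39% ± 0.497, glycine with 6.77% ± 0.628, methionine with 6.47% ± 0.522 and histidine with 4.97% ± 1.37 (n = 6 each). At the other end stood cysteine tRNAs with 0.268% ± 0.0472 over 29 entries, tryptophan with 0.115% ± 0.0149 over 7 entries, and asparagine with 0.00935% ± 0.00424 over 14 entries (n = 6 each). Leucine tRNA counts exceeded serine tRNA counts 1.64-fold, a log2 ratio of 0.71 ± 0.45 (n = 6; exact two-sided sign-flip permutation p = 0.03125, 6 of 6 libraries). The ratio was 0.32 ± 0.17 (n = 3) in the libraries with the lower totals and 1.10 ± 0.09 (n = 3) in those with the higher totals. Leucine and serine were picked as the leading and next isotypes of these same libraries, so the direction was largely set beforehand. The p-value is therefore no independent support for the lead of leucine.

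By anticodon, Leu(CAA) led with 16.8% ± 3.96 (SD, n = 6) of the tRNA counts. Its share ran from 11.7% to 14.2% in replicates 1 to 3 and from 20.03% to 20.9% in replicates 4 to 6. Ser(AGA) held 6.64% ± 1.38, Met(CAT) 6.47% ± 0.522, His(GTG) 4.97% ± 1.37, Ser(GCT) 4.73% ± 0.777, Leu(AAG) 4.44% ± 0.548 and Thr(AGT) 4.16% ± 0.348 (n = 6 each). In the higher-total libraries His(GTG) and Met(CAT), at 6.17% and 6.06%, had higher means than Ser(AGA) at 5.51% (n = 3 each), while in the lower-total ones Ser(AGA) came second at 7.76% (n = 3). In the lower-total libraries His(GTG), at 3.77%, stood below Ser(GCT) at 5.37%, Thr(AGT) at 4.40%, Leu(AAG) at 4.34% and Gly(GCC) at 3.87% (n = 3 each). Leu(CAA) exceeded Ser(AGA) 2.51-fold, a log2 ratio of 1.33 ± 0.64 (n = 6; exact permutation p = 0.03125, 6 of 6 libraries). That ratio was 0.78 ± 0.33 (n = 3) in the lower-total and 1.88 ± 0.05 (n = 3) in the higher-total libraries. This pair too was picked from the ranking in the same libraries, so its p-value is no independent support for the lead. Without the Leu(CAA) entry that had the most counts, a setting chosen after seeing the data, the log2 ratio of Leu(CAA) to Ser(AGA) was 0.93 (exact permutation p = 0.0625) and that of leucine to serine tRNAs 0.48 (exact permutation p = 0.0625).

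Ranks of the anticodons across the 6 libraries gave a Kendall's W of 0.981 over 51 anticodon names (permutation p = 1e-05, the smallest that 100000 resamples can give). This sets the ranks against random order only, over shares that span a wide range, and does not show that the order of neighbouring anticodons was stable. The shares themselves shifted between the sets of libraries. Of the 42 anticodons whose mean share is worth at least 10 counts in the smallest library, 9 had higher shares in all 3 higher-total libraries than in any lower-total library, and 12 had lower shares, where chance gives 10% in both directions together. The 9 rarer anticodons were left out of this count, a choice made after seeing the data. Over all 51 anticodons, 14 had higher and 14 had lower shares, though low depth can itself set the outcome for the rarer ones. His(GTG) was among those higher in the higher-total libraries, at 6.17% ± 0.501 against 3.77% ± 0.348 (n = 3 each), and Ser(AGA) among those lower, at 5.51% ± 0.227 against 7.76% ± 0.967 (n = 3 each). With 3 libraries against 3 the smallest exact two-sided p is 0.1, so no single anticodon could pass the threshold.

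**Figure D3:**
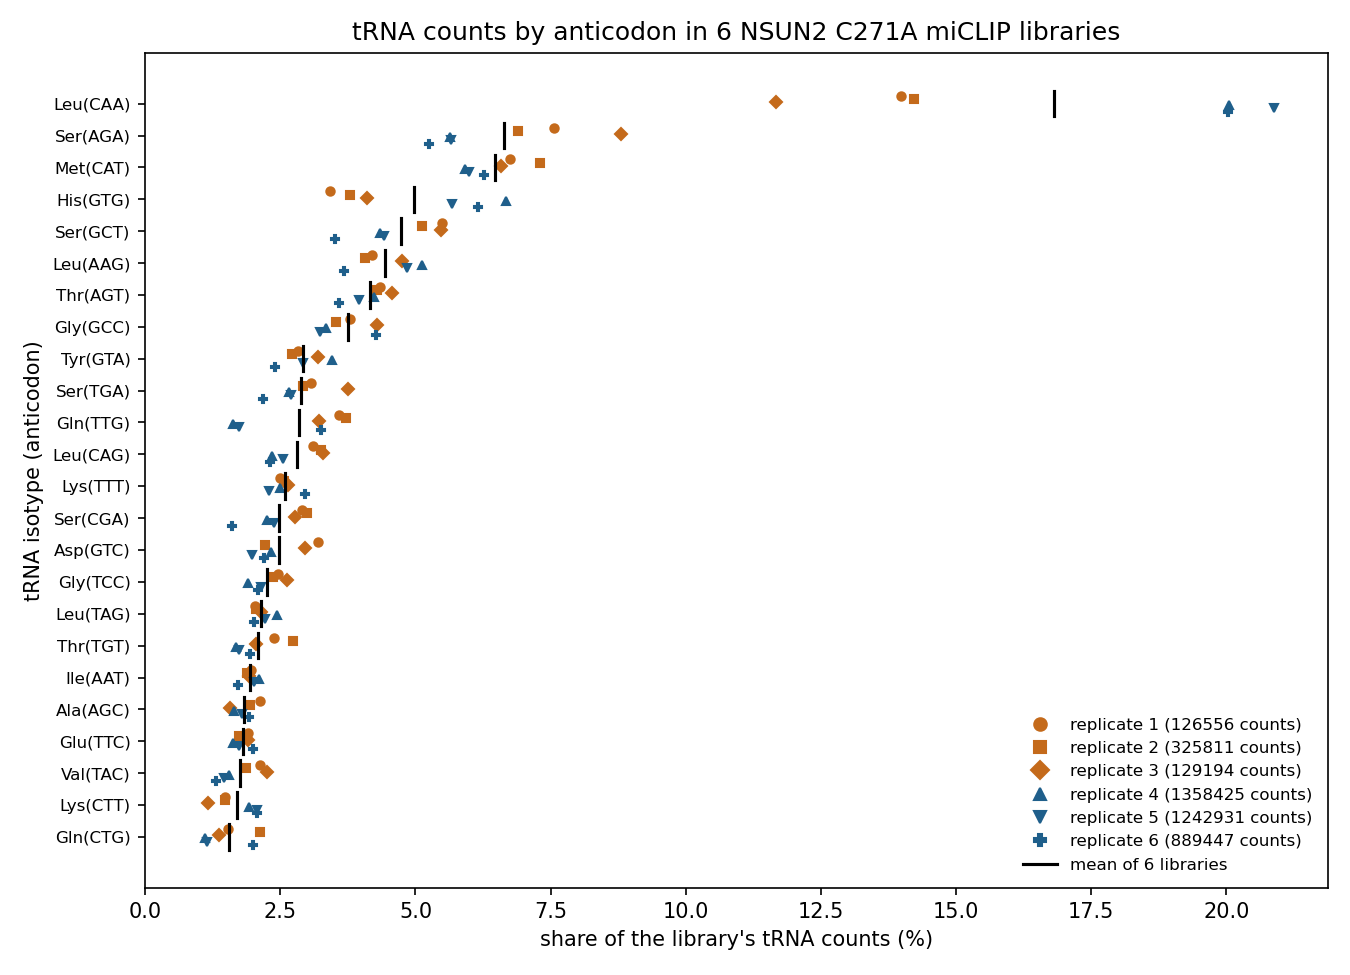
Share of each library's tRNA counts (percent, horizontal axis) for the 24 anticodons with the highest mean share (vertical axis). Each symbol is 1 of 6 libraries, orange for the 3 with the lower totals and blue for the 3 with the higher totals, and the black line is the mean. Leu(CAA) stands apart at 11.7% to 14.2% in the first set and 20.03% to 20.9% in the second, while Ser(AGA) is lower in the second set.

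Within Leu(CAA), 5 of 7 entries carried 99.9% of the counts, and over all 6 libraries these 5 entries had the highest mean shares of all counts. They were chr6.trna74 with 3.97% ± 0.828, chr6.trna100 with 3.78% ± 0.519, chr1.trna58 with 3.37% ± 0.793, chr6.trna140 with 2.65% ± 1.28 and chr6.trna141 with 2.65% ± 0.618 (SD, n = 6 each). The order differed in the lower-total libraries alone, where chr19.trna4, a Thr(AGT) entry named after its value was seen, stood with 2.77% above chr1.trna58 with 2.67% (n = 3 each), and chr6.trna140 ranked 12th, below 7 entries of other anticodons. The entry chr6.trna140 went from 1.48% ± 0.0206 (n = 3) in the lower-total libraries to 3.82% (n = 3) in the higher-total ones. The names give chromosomes 6 and 1, the notes name the GRCh37 build, and the tables give no start or end. Copies of one tRNA can be nearly identical in sequence and how reads matching several copies were counted is not given in the sources used here, so values of single copies are uncertain and the sums per anticodon are preferred.

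Of the microRNA entries, MI0016077 held 1.38% ± 0.0992 (SD, n = 6) of all counts, the highest share of any entry not named as a tRNA and 12th among all entries. It was followed by hsa-mir-1274b with 0.165% ± 0.0779, MI0016887 with 0.116% ± 0.0657, MI0016048 with 0.0525% ± 0.0260 and MI0016088 with 0.0167% ± 0.00562 (n = 6 each). The tables give no symbol for the 4 entries other than hsa-mir-1274b, and whether these 4 also derive from tRNA was not tested. The mean shares of hsa-mir-1274b, MI0016887 and MI0016048 were 0.109%, 0.0710% and 0.0333% in the libraries with the lower totals and 0.221%, 0.161% and 0.0716% in those with the higher totals (n = 3 each), a difference that was not tested. For MI0016887 the sets overlapped, with 0.0893% in replicate 6 and 0.106% in replicate 3.

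The lists of abundant small RNAs fixed in advance held few counts each, counted without RPPH1, RMRP, RN7SL1 and RN7SL2. The 5S rRNA family, the RNA polymerase III transcripts of the large ribosomal subunit, had 922 counts over 45 entries, a share of 0.0231% ± 0.00470 (SD, n = 6). Its leading members were RNA5SP202 with 425 counts and RNA5SP248 with 224, both annotated as pseudogenes, and RNA5S9 had 45. The 7SK family, whose RNA holds back the elongation factor P-TEFb, had 417 counts, of which 397 lay on the entry named 7SK. Its share was 0.00295% in the lower-total and 0.0115% in the higher-total libraries (n = 3 each). The Y RNA family had 128 counts, 91 of them on RNY1, and the U6 family had 7. Of these polymerase III RNAs, 20 had at least 3 counts in a library and 17 of the 20 belonged to the 5S family.

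Spliceosomal snRNAs had 425 counts, a share of 0.00785% ± 0.00390 (n = 6), and RNU2-2P was the only member found in all 6 libraries (202 counts). Their share was 0.00430% in the lower-total and 0.0114% in the higher-total libraries (n = 3 each). Small nucleolar RNAs had 378 counts, a share of 0.00890% ± 0.00327 (n = 6), with 228 on SNORD118, the U8 RNA of large-subunit rRNA processing, as the only member found in all 6. Small Cajal body RNAs had 32 counts. Among unclassified entries, ENSG00000252678 had 2801 counts and ENSG00000199916 had 191, and neither has a symbol in the tables used. Whether they are polymerase III RNAs was not tested. The first alone had more counts than the whole class of other polymerase III RNAs, which had 1474. The single rRNA entry, RNA5-8SP6, named here although it lies outside the naming rule, had 3, 2, 0, 77, 48 and 140 counts in replicates 1 to 6. Its mean share of 0.00471% ± 0.00579 (n = 6) became 0.00250% without replicate 6, and was 0.000995% in the lower-total and 0.00842% in the higher-total libraries (n = 3 each). The 0 counts in replicate 3 allow a share of up to 0.00232%.

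Entries found again in every library were 322 of 634, of which 304 were tRNA entries and 18 were others, and they carried 99.9% of all counts. Random lists of the same sizes, drawn in proportion to mean share, had 330 entries in common on average, between 321 and 342, and 998 of 1000 such lists reached or passed the observed number. The observed overlap was therefore not above that of random lists. The 18 others included hsa-vault-1, VTRNA1-3, VTRNA1-2, 7SK, SNORD118 and RNU2-2P. Another 141 entries had counts in a single library, none above 5 counts.

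Across entries, the 15 pairs of libraries had Pearson correlations of log2 shares from 0.903 to 0.992, with a median of 0.959, and Spearman correlations from 0.941 to 0.977, with a median of 0.952. These are correlations across RNAs, which are not independent replicates. All 15 pairs differed by more than counting error, with a chi-square statistic per degree of freedom from 9.36 to 115 and 0 pairs with a p over 0.05, so the planned averaging of libraries was not applied. The chi-square test treats every count as a separate molecule, and uncollapsed PCR copies would also raise it, so it does not show that the 6 tables come from 6 samples. The median difference between the 40 leading anticodons was 0.14 on the log2 scale within the sets of totals and 0.26 across them, and the ranges overlapped, reaching 0.25 within the sets and starting at 0.21 across them. The higher-total set was not uniform, since replicate 6 differed from replicates 4 and 5 with a chi-square statistic per degree of freedom of 112 and 98.8.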

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

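All tests of explanations in this part were chosen only after the results were seen, while the search for single libraries far from the others was planned. Of 103 values tested in this way, 7 had a library far from the other 5, where chance gives about 5.15. The share of the rRNA entry RNA5-8SP6 was 0.0157% in replicate 6 and at most 0.00567% in the others. Val(AAC) held 1.49% of tRNA counts in replicate 6 against 0.951% to 1.13% in the others. VTRNA1-3 held 0.0828% of counts in replicate 4 against 0.0607% to 0.0689% in the others. The remaining 4 rest on at most 4 counts each. RNA5SP65 stood at 0.00232% in replicate 3 with 3 counts, and RNA5SP442 at 0.00316% in replicate 1 with 4 counts and 0 in the others. RNA5SP500 stood at 0.000921% in replicate 2 with 3 counts, and a Y RNA entry (ENSG00000199303) at 0.000774% in replicate 3 with 1 count. No explanation was tested for these 7.

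The Leu(CAA) share of tRNA counts was 11.7% to 14.2% in the 3 libraries with the lower totals and 20.03% to 20.9% in the 3 with the higher totals. Counting error at the lower depth is argued against, because the higher-total libraries thinned to 126556 counts still held at least 19.7%, and so are the different entry lists, since each lower-total and higher-total library with the same list were at least 5.80 percentage points apart. A rise of Leu(CAA) that only dilutes the other tRNAs is argued against too, because with Leu(CAA) left out 16 of the 41 other anticodons worth at least 10 counts in the smallest library had shares that did not overlap between the sets, against at most 8 in any other of the 10 splits of 3 against 3, which are too few for a share under 0.05. The number in the table names went with the set in 6 of 6 libraries, so different numbers of PCR cycles may contribute, but cycles and totals cannot be told apart here, and thinning treats each count as a molecule, so the number of distinct molecules was not tested. The design has 1 group, so no biological explanation was tested.

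The log2 ratio of hsa-vault-1 to VTRNA1-3 was at least 2.34 in the libraries with the lower totals and at most 1.46 in those with the higher totals. Thinned to the smallest total, the higher-total libraries reached at most 1.75, and each lower-total and higher-total library with the same entry list stayed at least 0.88 apart, which argues against counting error and against the entry lists. The number of distinct molecules was not tested. Different numbers of PCR cycles stay open for the same reason as above, with 6 of 6 table names following the set. No biological explanation was tested.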

How the results depend on the processing

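The settings by totals, by Leu(CAA) and the comparison of tRNA with all other entries were chosen only after the results were seen. The comparison of VTRNA1-3 with VTRNA1-2 was not in the plan either, and the others were planned. Under settings that use all 6 libraries, 28 of 78 recomputed values moved by more than the spread between libraries and 2 no longer passed the threshold. The 520 values recomputed without some libraries say little about the stability of shares, because a mean over part of the libraries cannot move by the SD of all 6. No log2 ratio changed sign. Each was above 0 in 6 of 6 libraries, so leaving out libraries could not reverse any of them. Shares and correlations have no direction to change. The number of entries found in every library, 322, ran from 274 to 420, and Kendall's W from 0.9804 to 0.994. Leaving out a library ends all 6 calls by construction, since 5 libraries allow no p under 0.0625: the log2 ratios then ran from 5.43 to 5.47 for tRNA to all others, 1.79 to 2.12 for hsa-vault-1 to VTRNA1-3, 3.86 to 4.47 for hsa-vault-1 to VTRNA1-2, 2.07 to 2.41 for VTRNA1-3 to VTRNA1-2, 0.61 to 0.83 for leucine to serine and 1.21 to 1.51 for Leu(CAA) to Ser(AGA) tRNAs. In the same order, the 3 lower-total libraries gave 5.46, 2.61, 5.26, 2.65, 0.32 and 0.78 and the 3 higher-total ones 5.45, 1.30, 3.22, 1.92, 1.10 and 1.88, where 3 libraries allow no exact p under 0.25. Without the top Leu(CAA) entry the last pair became 0.48 and 0.93 (exact permutation p = 0.0625 each); the cause was not tested. The median Spearman correlation was 0.977 over entries with counts in both libraries and 0.974 within the lower totals, and the median Pearson correlation was 0.984 within the higher totals. Counted as shares of entries instead of counts, a different quantity by construction, tRNA held 83.7%, vault RNA 0.767%, other polymerase III RNA 6.41%, sn-, sno- and scaRNA 4.54%, rRNA 0.187%, microRNA 2.68% and unclassified entries 1.67%. Without the top RNA of each class, the shares were 99.5% for tRNA, 0.0871% for vault RNA, 0.0260% for other polymerase III RNA, 0.380% for microRNA and 0.00573% for unclassified entries, since single entries such as MI0016077 and hsa-vault-1 carry much of their class. With at least 10 counts per entry, other polymerase III RNA held 0.0194% and sn-, sno- and scaRNA 0.00921%. As shares outside tRNA, larger by construction, hsa-vault-1 held 12.8%, VTRNA1-3 3.02%, VTRNA1-2 0.654%, 5S rRNA 1.03%, 7SK 0.323%, Y RNA 0.127%, U6 0.0151%, spliceosomal snRNAs 0.351%, snoRNAs 0.395% and scaRNAs 0.0251%. Outside Leu(CAA), VTRNA1-3 held 0.0809%. As means per listed tRNA entry, leucine held 20.8% and serine 13.3%. Averaging libraries that agree within sampling noise gave no value, because every pair differed by more than counting error, a test that uncollapsed PCR copies would also fail. The settings for the NSUN2 transcript and for crosslink positions, and the planned comparison with protein-coding RNA, were not run. Depth limits the rare RNAs: below about 3 counts, or 0.00237% in replicate 1, no difference was detectable.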

Other observations

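All tests in this part were chosen only after the results were seen. Most tRNA isotypes held fewer counts than their number of entries would give, and leucine, histidine, serine, methionine, threonine and glycine tRNAs held more. All 634 listed entries had counts in some library, so the number of entries may depend on detection and is not a number of gene copies. The share of tRNA counts divided by the share of tRNA entries was 4.11 for leucine, 2.63 for histidine and 2.62 for serine, the first 3 of 20 isotypes. The order of histidine and serine turned between the sets, with 1.99 against 3.02 in the lower-total and 3.26 against 2.22 in the higher-total libraries, while leucine led in both with 3.63 and 4.60. Over entries with counts in all libraries alone, the values were 3.45 for leucine and 1.96 for serine. Of these 304 entries histidine tRNAs had 6, with 4.97% of tRNA counts, and serine tRNAs 26, with 16.7%, which puts histidine above serine. Alanine tRNAs, with 7.09% of the entries, held 2.91% of the counts, and lysine tRNAs, with 8.51% of the entries, held 4.28%. Cysteine tRNAs held 0.268% of the counts over 6.86% of the entries.

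Gln(TTG) crossed the sets of libraries. It held 3.26% of tRNA counts in replicate 6, close to the 3 lower-total libraries with a mean of 3.51% ± 0.261 (SD, n = 3), while the mean of the 3 higher-total libraries was 2.20% ± 0.916. Arginine tRNAs were split by anticodon. Arg(ACG) held 1.10% ± 0.107 of tRNA counts and Arg(TCT) 0.209% ± 0.0598, while Arg(CCT) held 0.00764% ± 0.00482 and Arg(TCG) 0.00641% ± 0.00421 (SD, n = 6 each). For Arg(TCT), 94.9% of the share lay on 1 entry.

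The excess of leucine and serine tRNAs did not rest on a single listed entry. Without the top entry of each isotype the lower value was 2.44, above 1 in every library. How reads matching several copies were counted is not given, so a single source spread over nearly identical copies was not excluded. Leucine and serine tRNAs share a long variable arm, and 9 of their 10 anticodons exceeded their share of entries against 9 of 38 others, which is no test of the arm because the pair was picked from the same ranking. Selenocysteine tRNA, left out of both of these numbers, also has a long arm, and its 1 entry had 21 counts, below its share of entries. With it, 9 of 11 long-arm anticodons exceeded their share. Histidine tRNAs without such an arm had more than their share too, so an excess also occurred without the arm. Whether the arm contributes for leucine and serine tRNAs cannot be told here. Without a library of unselected RNA, an excess cannot be told apart from abundance in the cells. No biological explanation was tested.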
